A study of Panax vietnamensis with 6 samples.

How the data were processed

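RNA sequencing libraries were made from leaves and roots of 1-year-old Panax vietnamensis (Vietnamese ginseng), 4 from leaves and 2 from roots. Per the labels, tissue was frozen in liquid nitrogen, total RNA was extracted with a column kit and libraries followed a standard Illumina protocol. The labels carry the numbers 2, 5, 6 and 8 for leaves and 2 and 8 for roots. They do not say what a number marks or whether libraries came from separate plants, so p-values measure the spread between these libraries, which may be technical.

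The deposited table of the whole series gives, per the file headers, a read count and an FPKM value for each of 263424 contigs in each library. The submitters' processing notes name Trimmomatic 0.38, Bowtie 1.1.2 and RSEM, without roles. The assembler, the filters and any genome build are not given in the sources used here. Because RSEM estimates counts, the deposited counts were read as estimated counts, and they were whole numbers as deposited, so no rounding was needed. The deposited FPKM values (fragments per kilobase of contig, scaled to library depth), as titled per the file headers, served only in an alternative test. The table held 0 columns of per-library values that could not be matched to a sample. Contigs were named as the table names them, and protein names are the descriptions of the best database hit in the same table. Contigs of a de novo assembly can be fragments of a gene or merged copies, so reads of near-identical paralogs (glycosyltransferases, cytochromes P450, heat shock proteins, histones) may be split between contigs.

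Each library also has a separate file whose contigs are named independently of the whole-series table. For number 2, the separate file recorded under the leaf sample is named as the root and the reverse. The whole-series columns were therefore matched to samples by their titles for every main value. The exchange of both number 2 libraries and their removal were alternatives. The separate files were used only to compare their counts, summed by best protein hit, with the columns of the whole-series table.

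Depth ranged from 15004999 counts in leaves 2 to 22227041 in roots 8. Shares of counts carry Wilson 95% intervals, and a count of 0 allows up to 3 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise: the lowest chi-square per contig was 87.9, between leaves 5 and leaves 8.

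Each contig was placed in a class (land plant, rust fungus, other fungus, animal, nematode, protist, alga, organelle genome, rRNA repeat, unclassified, no annotation) from the organism code of its eukaryotic pathway database hit, with 442 codes sorted by hand. A contig without a usable code took the class of over 80% of the coded contigs with the same best-hit organism, where there were at least 5. No class for bacteria or viruses could be formed this way. These classes, and the restriction of the plant gene lists to land plant contigs, were made after the data were examined.

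Roots were compared with leaves by edgeR 4.0.16 under R 4.3.3, with TMM factors, filterByExpr, the quasi-likelihood F test and a model with tissue alone. Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are log2 values of roots against leaves with standard errors derived from the F statistic, and CPM values use TMM-scaled library sizes. The TMM factor was 0.640 in roots 2 and 0.900 to 1.26 in the other libraries. CPM values of roots 2 are therefore raised the most relative to its plain share of counts. The common biological coefficient of variation was 0.825.

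The test, most alternatives, the rule for named genes and the terms of 19 gene lists were written before the data were examined. The lists were photosystems, Calvin cycle and photorespiration, chlorophyll and carotenoid synthesis, mevalonate pathway, triterpene saponins, MEP pathway, phytosterols, phenylpropanoids, flavonoids, starch and sucrose, nutrient and water transport, root barrier, leaf epidermis, storage and defence, heat shock and dehydration (as a marker of sample handling), ribosomal proteins, cell division, organ identity factors, and transcripts of other organisms. How the terms were matched to descriptions was not fixed beforehand. It took 3 rounds, made with values of single libraries on screen, and the third was used for all list results. For triterpene saponins these rounds matched 19, 82 and 42 contigs, and the call depends on the round, so the report gives all 3 results. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with an estimated correlation, and with fry.

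Abundance was ranked by mean log2 CPM across all libraries. Named genes were the most abundant tested contig for each of 10 enzymes of triterpene and sterol synthesis and for each list. To these were added the 5 largest rises and 5 largest falls among called contigs with a protein name, a mean log2 CPM of at least 5 and no overlap between the tissues. The search patterns for the 10 enzymes were written after the data were examined. Called list members and protein families outside this rule were chosen after their values were seen.

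The alternatives set beforehand were the number 2 exchange and removal, numbers 2 and 8 alone, number as a block, median-ratio size factors, library size alone, no count filter, a CPM of at least 1 in at least 2 libraries, DESeq2 1.42.0, limma-voom, and limma on log2(FPKM + 1), with pseudocounts of 0.1 and 5 besides. The rest were a fold minimum of 1 on the log2 scale, an adjusted p under 0.01, sums by best protein hit, leaving out contigs of other organisms, organelle genomes and rRNA, and each library left out in turn. The 10 most abundant contigs were also left out of the shares of counts. Alternatives chosen after seeing the data were both earlier rounds of list matching and a fit without the 10 most abundant contigs. Where 1 root remained, its spread was taken from the leaves.

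The procedure was tested on simulated counts for the 34830 tested contigs, of which 200 were changed, 50 at each fold. At the folds chosen first, 0 of 50 were recovered at a fold of 2, 0 at 4, 1 at 8 and 9 at 16, with 1 false call among 11. Because so few were recovered, larger folds were then added: 1 of 50 was recovered at a fold of 4, 16 at 16, 33 at 64 and 44 at 256, with 3 false calls among 97. The simulation drew on the spread of the real libraries, so it followed the comparison. Of 50 random sets passed through camera in each simulation, 0 were called, and a set of raised contigs was called in both. Simulated contigs vary independently, so this does not test camera on correlated genes.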

Results

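Messenger RNA was profiled in leaves and roots of 1-year-old Panax vietnamensis, a ginseng species that makes triterpene saponins (ginsenosides). There were 4 leaf libraries, numbered 2, 5, 6 and 8, and 2 root libraries, numbered 2 and 8. Leaves 2 held 15004999 counts, leaves 5 held 17959809, leaves 6 held 15142474 and leaves 8 held 16730324. Roots 2 held 19174348 counts and roots 8 held 22227041. Contigs of land plants took 88.7 ± 2.32% of the counts in leaves (SD, n = 4) and 90.6 ± 1.31% in roots (SD, n = 2). Transcripts of the organelle genomes took 1.39 ± 0.574% in leaves and 0.363 ± 0.0839% in roots, and 0.850% and 0.365% without the 10 most abundant contigs. All fold changes are on the log2 scale, roots against leaves, with the standard error, and levels are TMM-normalised CPM, given as mean ± SD with n = 4 for leaves and n = 2 for roots.

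The organ markers of each library were read first, because names and records of the number 2 files disagreed on which was leaf and which was root. Nuclear photosystem transcripts, which encode the light-harvesting machinery, summed to 16797 CPM in leaves 2, 2965 in leaves 5, 2111 in leaves 6 and 1853 in leaves 8. They summed to 1763 CPM in roots 2 and 599 in roots 8. Transcripts of the root barrier (Casparian strip and suberin) summed to 2802 CPM in roots 2 and 431 in roots 8, and to between 270 and 383 in the leaves. By both lists the whole-series columns titled leaves 2 and roots 2 carried the markers of their titles, with the photosystem sum of roots 2 close to that of leaves 8. Leaves 2 stood apart: its Pearson correlation of log2 CPM across contigs was 0.834 with roots 2 and 0.778 to 0.804 with the other leaves. Leaves 5 and leaves 8 reached 0.922 and both roots 0.846. Contigs are not independent replicates, so these correlations carry no p-value.

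**Figure D1:**
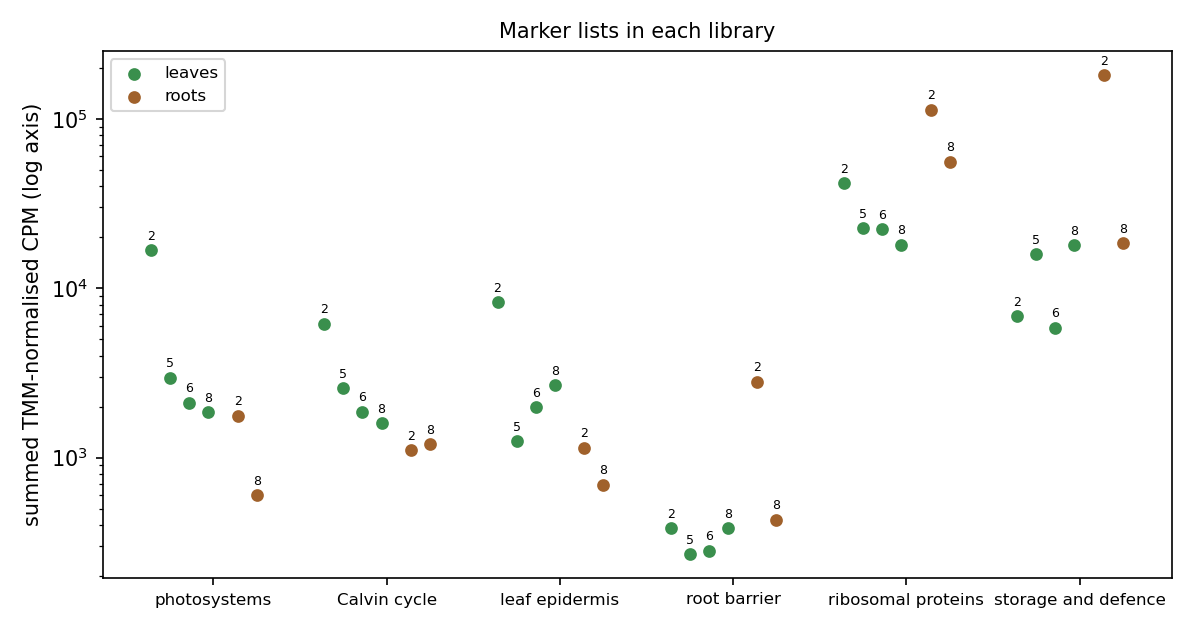
Summed TMM-normalised CPM of 6 gene lists in each library (log axis), with leaves in green, roots in brown and the library number above each point. Photosystem sums ranged from 1853 to 16797 CPM in leaves and from 599 to 1763 CPM in roots.

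The comparison of roots with leaves asked which transcripts differ between the organs of the young plant. Among named genes, early light-induced protein 1, a chlorophyll-binding protein of chloroplast development and light stress, was higher in roots (1115 ± 677 CPM) than in leaves (10.4 ± 2.62 CPM). So were alcohol dehydrogenase 2, an enzyme of fermentation, and a class IV small heat shock protein, a chaperone. The latter belongs to the list whose terms were set beforehand as a marker of sample handling. Leaves had more ECERIFERUM 3, an enzyme of cuticular wax synthesis, and more galactinol synthase 1, which makes the donor of raffinose sugars. In edgeR, 172 of 34830 tested contigs passed at an adjusted p under 0.05 (0.494%), of which 116 were higher in roots and 56 lower. Of these, 155 were land plant contigs, and 41 had 3 or fewer counts in 1 of the tissues. The smallest absolute change among them was 2.70. Their adjusted p ran from 0.0138 upward with a median of 0.0406, so many calls lay near the threshold and 0 were under 0.01. At an unadjusted p under 0.05 there were 5573 contigs.

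These calls rested on nearly every library. In edgeR, with 172 contigs called from all 6 libraries, 1029 passed without leaves 2, 27 without leaves 8 and 5 without roots 8. Without leaves 5, leaves 6 or roots 2, 0 contigs passed in edgeR, with 3750, 4280 and 3194 at an unadjusted p under 0.05. The median adjusted p of the 172 contigs was 0.120 without leaves 5, 0.135 without leaves 6 and 0.256 without roots 2, and all 172 kept their direction whichever of the 6 libraries was left out. From the 6 libraries, DESeq2 called 2753 contigs (1326 higher, 1427 lower) and limma-voom 183 (143 higher, 40 lower). With the number 2 libraries exchanged between leaf and root, 0 contigs passed in edgeR (1597 at an unadjusted p under 0.05). With both left out, 0 passed as well (6105 at an unadjusted p under 0.05). Scaling by library size alone gave 165 contigs, 93 higher and 72 lower, and moved the median change of all tested contigs from -0.13 to -0.42. The contigs tested and their median change also differed between settings, so counts and list medians are not directly comparable. Without roots 2, 51655 were tested (median -0.72), without roots 8 50422 (-1.38) and without both number 2 libraries 49676 (-0.63). With no count filter the median of 168446 was -2.28. Without leaves 5 and leaves 6, 31713 and 32191 were tested.

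Named genes with the largest rises were early light-induced protein 1 (c774557_g3_i1, 6.74 ± 0.62, adjusted p 0.0138), the class IV small heat shock protein (c494485_g1_i1, 5.34 ± 0.74, adjusted p 0.0357) and alcohol dehydrogenase 2 (c742346_g1_i1, 5.31 ± 0.64, adjusted p 0.0271). The small subunit of a heterodimeric geranylgeranyl pyrophosphate synthase, an isoprenoid enzyme of plastids, rose by 5.10 ± 0.66 (c379167_g1_i1, adjusted p 0.0326). The subtilisin-like protease SBT1.7 rose by 4.35 ± 0.52 (c744652_g1_i1, adjusted p 0.0251). The heat shock protein change was 3.85 without roots 2, that of early light-induced protein 1 was 5.92 and that of SBT1.7 was 3.71. The synthase change was 4.13 without roots 8. The 5 calls were lost without leaves 5 (adjusted p 0.0695 to 0.143), leaves 6 (0.0846 to 0.150) and roots 2 (0.0688 to 0.144). Without leaves 8 or roots 8, early light-induced protein 1 alone passed (adjusted p 0.0462 and 0.0331). With the number 2 libraries exchanged none of the 5 passed (adjusted p 1.00). The changes of early light-induced protein 1 (-0.32), the heat shock protein (-1.19) and SBT1.7 (-0.09) then turned negative, and those of alcohol dehydrogenase 2 and the synthase were 0.90 and 2.44. With counts summed by protein, the synthase (0.124) and SBT1.7 (0.0815) did not pass.

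Named genes with the largest falls were led by galactinol synthase 1 (c756061_g1_i1), at 1102 ± 741 CPM in leaves and 1 count in both roots together. The ratio of leaves to roots over pooled counts, scaled by library totals without TMM factors, was 51904 (exact 95% interval 9315 to 2050115, counting error only). In edgeR, with TMM factors, the fold was 30256 (adjusted p 0.0205). GBR3, named in the annotation without a function, fell by 9.96 ± 1.14 (c796492_g2_i2, adjusted p 0.0227), from 2064 ± 981 CPM in leaves to 2.04 ± 1.27 in roots. CASP-like protein 1, a membrane protein related to those of the Casparian strip, fell by 9.08 ± 0.84 (c47012_g1_i1, adjusted p 0.0138). ECERIFERUM 3 fell by 8.25 ± 0.86 (c778093_g1_i1, adjusted p 0.0182) and asparagine synthetase, which stores nitrogen in an amide, by 6.97 ± 1.14 (c796009_g2_i4, adjusted p 0.0497). These calls were lost without leaves 5 (adjusted p 0.0639 to 0.136), leaves 6 (0.0846 to 0.101), roots 2 (0.0809 to 0.480) and roots 8 (0.0578 to 0.185). Without leaves 8, GBR3 (0.0501) and asparagine synthetase (0.0722) did not pass, nor did the latter by limma-voom (0.0566) or with counts summed by protein (0.0542). The change of CASP-like protein 1 was -9.87 without roots 2 and that of GBR3 was -10.77 without roots 8. With the number 2 libraries exchanged none of the 5 passed (adjusted p 1.00), with changes from -1.49 to -0.24.

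Gene lists were next compared as groups. Of 19 lists, 13 passed in camera at its preset correlation, 9 towards roots and 4 towards leaves. With an estimated correlation 0 passed in camera (adjusted p 0.239 to 0.874), and 2 had an unadjusted p under 0.05. By fry 0 passed (lowest adjusted p 0.0769), and 6 had an unadjusted p under 0.05. With the number 2 libraries exchanged, 8 lists passed in camera and the medians of 10 changed sign.

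**Figure D2:**
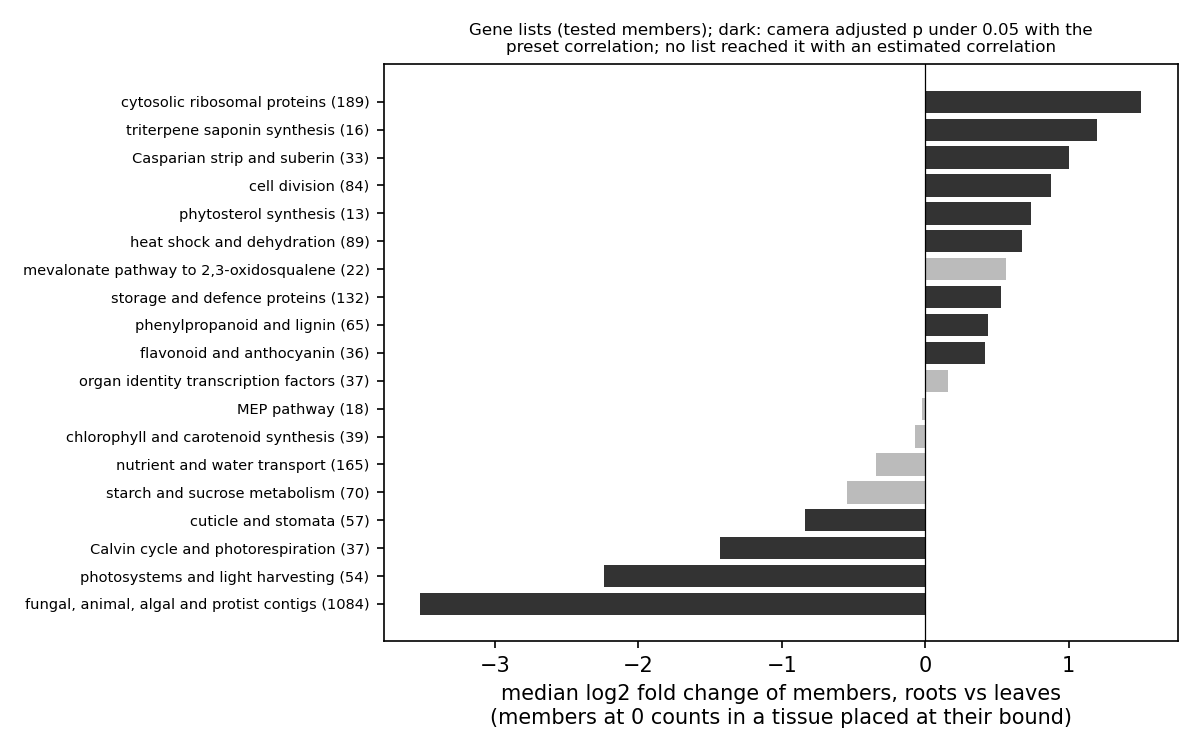
Median log2 fold change of roots against leaves for the tested contigs of each of 19 gene lists, with contigs at 0 counts in 1 tissue set at their bound. Dark bars mark the 13 lists with an adjusted p under 0.05 in camera at the preset correlation, and medians run from -3.52 (other organisms) to 1.51 (ribosomal proteins).

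Photosynthesis transcripts were lower in roots as a group. The 54 tested photosystem contigs of 166 matched had a median of -2.24 (camera adjusted p 1.13e-04, adjusted p = 0.433 with an estimated correlation). In edgeR 0 of them passed over all contigs and 6, all lower, when adjusted over the list alone. At an unadjusted p under 0.05, 3 were higher and 20 lower, DESeq2 called 2 higher and 9 lower, and limma-voom 0. The most abundant, the photosystem II 10 kDa polypeptide (c797256_g1_i1), averaged 699 ± 736 CPM in leaves and 105 ± 93.3 in roots (adjusted p 0.287 in edgeR). The median was -0.42 without leaves 2, -3.78 without roots 2 and -2.41 without roots 8, where the call was lost. For all contigs tested without roots 2 and roots 8 the medians were -0.72 and -1.38. With the number 2 libraries exchanged the list median was 1.41.

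Calvin cycle and photorespiration transcripts, which fix carbon and recycle the products of oxygenation, had a median of -1.43 over 37 tested contigs of 77 matched. The camera adjusted p was 3.55e-05, and adjusted p = 0.298 with an estimated correlation. The list summed to 6164 CPM in leaves 2, between 1593 and 2570 in the other leaves, 1106 in roots 2 and 1201 in roots 8. Of these contigs 2 fell in edgeR, and 4 were higher and 16 lower when adjusted over the list alone. Both that fell were chosen after their values were seen: glyceraldehyde-3-phosphate dehydrogenase B (c794076_g1_i1, 134 ± 95.7 CPM in leaves, 0.0815 ± 0.115 in roots) and phosphoribulokinase (c736256_g1_i1, 75.6 ± 63.7 CPM in leaves, 0.0806 ± 0.114 in roots). Their calls were lost without leaves 5 (adjusted p 0.120), leaves 6 (0.138 to 0.150), roots 2 (0.295 to 0.360) and roots 8 (0.131 to 0.162), and 1 was lost without leaves 8 (0.0504). The most abundant member, a peroxisomal 2-hydroxy-acid oxidase (c803739_g4_i4), was at 226 ± 45.9 CPM in leaves and 284 ± 77.7 in roots (adjusted p 0.780). The list median was -0.76 without roots 2 and -0.77 without both number 2 libraries, against -0.72 and -0.63 for all contigs tested then. The call was lost without both number 2 libraries, and the median was 0.43 with them exchanged (adjusted p 0.218).

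Chlorophyll and carotenoid synthesis showed no shift that passed: 39 of 68 matched contigs were tested, with a median of -0.07 and a mean of 0.07 (camera adjusted p 0.662). In edgeR 0 passed, 1 was lower when adjusted over the list alone, and 4 were higher and 3 lower at an unadjusted p under 0.05. DESeq2 called 2 higher and 2 lower, and limma-voom 0. Beta-carotene hydroxylase 2 (c775997_g1_i2), its most abundant member, was at 115 ± 89.2 CPM in leaves and 81.3 ± 81.2 in roots. The median was 0.46 without leaves 2.

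Leaf epidermis transcripts (cuticle, wax and stomata) were lower in roots, with a median of -0.84 over 57 tested contigs of 126 matched (camera adjusted p 0.00142, adjusted p = 0.418 with an estimated correlation). In edgeR 4 fell and 1 rose, and 21 were lower and 9 higher when adjusted over the list alone. The list summed to 8257 CPM in leaves 2, 1253 in leaves 5, 1984 in leaves 6 and 2673 in leaves 8, and to 1144 in roots 2 and 692 in roots 8. Besides ECERIFERUM 3, and chosen after their values were seen, ECERIFERUM 1 (c759989_g2_i3, 26 ± 21.7 CPM in leaves, 0.202 ± 0.0556 in roots) and ECERIFERUM 2 (c787125_g1_i1, 75.3 ± 60.7 and 0.0408 ± 0.0577) fell. So did 3-ketoacyl-CoA synthase 12, which elongates fatty acids for wax (c854324_g1_i1, 117 ± 51.9 and 0.163 ± 0.116). Non-specific lipid-transfer protein 8, also chosen after its values were seen, rose (c498696_g1_i1, 5.94 ± 5.13 CPM in leaves and 199 ± 34.8 in roots). The most abundant lipid-transfer protein (c653069_g1_i1) was at 1410 ± 1553 CPM in leaves and 51.0 ± 46 in roots (adjusted p 0.170). All 5 calls were lost without leaves 5 (adjusted p 0.0639 to 0.139), leaves 6 (0.0846 to 0.135), roots 2 (0.119 to 0.441) and roots 8 (0.0725 to 0.182), and 2 held without leaves 8 (lowest adjusted p 0.0360). The list median was -3.64 without roots 2 and -1.14 without roots 8, against -0.72 and -1.38 for all contigs tested then. The list call was lost without roots 8, and the median was 0.49 with the number 2 libraries exchanged. The list call was also lost with no count filter (adjusted p 0.737) and on log2(FPKM + 5) (0.209).

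Root barrier transcripts were higher in roots, with a median of 1.00 over 33 tested contigs of 62 matched (camera adjusted p 0.00191, adjusted p = 0.298 with an estimated correlation). In edgeR 1 rose, and 10, all higher, passed when adjusted over the list alone. The riser, chosen after its values were seen, was omega-hydroxypalmitate O-feruloyl transferase (c726317_g1_i1, adjusted p 0.0440), which esterifies suberin, at 0.213 ± 0.175 CPM in leaves and 15.1 ± 9.81 in roots. Its call was lost without leaves 5 (adjusted p 0.144), leaves 6 (0.151), leaves 8 (0.0931), roots 2 (0.480) and roots 8 (0.0999). The most abundant member, dirigent protein 21 (c724289_g1_i1), had a change of 0.05 that turned to -0.60 under library size alone. Barrier transcripts summed to 2802 CPM in roots 2 but 431 in roots 8. The list median was 0.34 without roots 2, against -0.72 for all contigs tested then. It was 1.67 without leaves 6 and -0.63 with the number 2 libraries exchanged (adjusted p 0.928).

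Triterpene saponin transcripts were higher in roots by the list as finally matched, with a median of 1.2 over 16 tested contigs of 42 matched (camera adjusted p 0.00877, adjusted p = 0.298 with an estimated correlation). This call depended on how list terms were matched: the first round gave an adjusted p of 0.282 over 2 tested contigs of 19 matched, and the second 0.468 over 43 of 82. In edgeR 1 contig rose and 1 fell, and 2 were higher and 1 lower when adjusted over the list alone. Both were chosen after their values were seen. Beta-amyrin 28-oxidase (c726100_g1_i1, adjusted p 0.0369), which oxidises the oleanane skeleton, was at 0.310 ± 0.520 CPM in leaves and 191 ± 0.255 in roots. UDP-glycosyltransferase 71E1 (c796407_g4_i1, adjusted p 0.0227), of a family that attaches sugars, was at 112 ± 30.2 CPM in leaves and 0.323 ± 0.341 in roots. These calls were lost without leaves 5 (adjusted p 0.0803 to 0.124), leaves 6 (0.101 to 0.144), roots 2 (0.135 to 0.222) and roots 8 (0.0623 to 0.103), and 1 was lost without leaves 8 (0.0501). The list median was 0.58 without roots 2, against -0.72 for all contigs tested then. It was 1.91 without leaves 6 and 0.19 with the number 2 libraries exchanged (adjusted p 0.842).

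Of the 10 pathway enzymes, whose contigs were found with search patterns written after the data were examined, 0 passed in edgeR, 4 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. Their changes ranged from 0.06 for squalene epoxidase (c780573_g1_i4), which turned to -0.65 under library size alone, to 2.94 ± 1.13 for protopanaxadiol 6-hydroxylase (c577086_g1_i1, adjusted p 0.269), the enzyme that makes protopanaxatriol. The latter was at 1456 CPM in roots 2, 94.2 in roots 8 and 101 ± 113 in leaves. HMG-CoA reductase (c794138_g5_i1), a regulated step of the mevalonate pathway, was at 27.5 ± 25.9 CPM in leaves and 171 ± 131 in roots (adjusted p 0.224). Dammarenediol synthase (c762312_g1_i2), which forms the dammarane skeleton, was at 31.3 ± 37.6 CPM in leaves and 80.2 ± 87.2 in roots (adjusted p 0.569). Beta-amyrin synthase (c800722_g2_i1) was at 1.57 ± 1.18 and 8.88 ± 0.248 CPM (adjusted p 0.211). The other 5 enzymes were farnesyl diphosphate synthase (c777193_g1_i5, 2.45), squalene synthase (c802035_g3_i1, 1.11), dammarenediol 12-hydroxylase (c726099_g1_i2, 1.73), another beta-amyrin 28-oxidase (c741822_g1_i3, 1.03) and cycloartenol synthase (c802137_g1_i12, 0.66), with adjusted p from 0.175 to 0.600. Several turned negative without roots 2, among them squalene epoxidase (-1.86), dammarenediol synthase (-0.76), squalene synthase (-0.76) and protopanaxadiol 6-hydroxylase (-0.11).

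Upstream, the mevalonate list did not pass (22 of 54 matched contigs tested, median 0.56, camera adjusted p 0.0543), but its most abundant member rose. This was acetyl-CoA acetyltransferase (c801217_g7_i1), the first step of the pathway, at 98.8 ± 25.4 CPM in leaves and 895 ± 279 in roots (3.18 ± 0.49, adjusted p 0.0448 in edgeR). It was also the 1 contig called when adjusted over the list alone. Its call was lost without leaves 5 (adjusted p 0.151), leaves 6 (0.165), leaves 8 (0.141), roots 2 (0.256) and roots 8 (0.0869), under library size alone (0.0637) and with counts summed by protein (0.0600). Among other settings, the list passed without roots 8 (median 0.68) and with terms as first matched (adjusted p 0.0493). Its median was -0.20 without roots 2, against -0.72 for all contigs tested then.

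Phytosterol synthesis, which shares 2,3-oxidosqualene with the saponins, was higher in roots over 13 tested contigs of 23 matched (median 0.74, camera adjusted p 0.00312, adjusted p = 0.433 with an estimated correlation). In edgeR 0 passed, 1 was higher when adjusted over the list alone, and 5 were higher at an unadjusted p under 0.05. DESeq2 called 1 higher and limma-voom 0. Delta(24)-sterol reductase (c748056_g1_i1), the most abundant, was at 52.5 ± 8.40 CPM in leaves and 77.3 ± 43.1 in roots. The call was lost without roots 2 (median 0.03, against -0.72 for all contigs tested then). It was also lost without both number 2 libraries, and the median was -0.20 with these exchanged. The plastid route to isoprenoids, the MEP pathway, did not pass over 18 tested contigs of 33 matched (median -0.02, mean 0.00, camera adjusted p 0.610). In edgeR 0 passed over all contigs or adjusted over the list alone, 2 were higher at an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0. Its most abundant member, 4-hydroxy-3-methylbut-2-en-1-yl diphosphate synthase (c798834_g1_i1), was at 102 ± 50.1 CPM in leaves and 102 ± 92.6 in roots. The list median was 0.16 without leaves 6.

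Flavonoid transcripts were shifted towards roots by the median over 36 tested contigs of 78 matched (0.42, camera adjusted p 1.95e-04, adjusted p = 0.239 with an estimated correlation). Their sum was not higher in roots (1868 ± 207 CPM) than in leaves (2001 ± 1089 CPM). In edgeR 2 rose, and 9 were higher and 2 lower when adjusted over the list alone. Those 2, chosen after their values were seen, were chalcone synthase 2 (c772653_g2_i1, 0.440 ± 0.289 CPM in leaves, 181 ± 61.4 in roots), the entry enzyme of the pathway, and flavonoid 3'-monooxygenase (c771817_g1_i1, 0.141 ± 0.0898 and 82.2 ± 26.6). Both had an adjusted p of 0.0138. Their calls were lost without leaves 5 (adjusted p 0.0639 to 0.0695), leaves 6 (0.0846 to 0.0944), roots 2 (0.0581 to 0.0809) and roots 8 (0.0520 to 0.0623). The most abundant member, flavanone 3-dioxygenase 2 (c777241_g1_i1), was at 1416 ± 1043 CPM in leaves and 125 ± 17.6 in roots (adjusted p 0.158). With the number 2 libraries exchanged the list no longer passed (adjusted p 0.144).

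Phenylpropanoid and lignin transcripts passed narrowly (65 tested of 142 matched, median 0.44, camera adjusted p 0.0487, adjusted p = 0.417 with an estimated correlation). In edgeR 1 rose, the feruloyl transferase named with the root barrier, and 1 was higher and 1 lower when adjusted over the list alone. Shikimate O-hydroxycinnamoyltransferase (c777502_g2_i1), a lignin enzyme and the most abundant member, was at 1291 ± 1292 CPM in leaves and 2326 ± 280 in roots (adjusted p 0.673). The list call was lost without leaves 5 (adjusted p 0.258), leaves 6 (0.0986) and roots 8, and with a CPM of at least 1 required in 2 libraries (0.337). Without roots 8 the list median was -0.34, against -1.38 for all contigs tested then. The call was also lost from numbers 2 and 8 alone (0.698), on log2(FPKM + 1) (0.0626) and with counts summed by protein (0.0871).

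Ribosomal protein transcripts had the largest upward shift of the 19 lists. The 189 tested contigs of 840 matched had a median of 1.51, with 181 higher in roots (camera adjusted p 1.39e-25, adjusted p = 0.298 with an estimated correlation). In edgeR 0 passed over all contigs, and 40 higher and 1 lower passed when adjusted over the list alone. At an unadjusted p under 0.05, 96 were higher and 2 lower, DESeq2 called 39 higher and 1 lower, and limma-voom 2 higher. The list summed to 113058 CPM in roots 2, 55798 in roots 8 and 26142 ± 10489 in leaves. Ribosomal protein L32-1 of the 60S subunit (c661731_g1_i1) was at 1354 ± 357 CPM in leaves and 2387 ± 609 in roots. The median was 0.82 without roots 2, against -0.72 for all contigs tested then. With the number 2 libraries exchanged the list median was -0.01, against -0.19 for all contigs.

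Cell division transcripts were higher over 84 tested contigs of 232 matched (median 0.88, camera adjusted p 2.48e-05, adjusted p = 0.418 with an estimated correlation). In edgeR 0 passed over all contigs or adjusted over the list alone, 23 were higher and 4 lower at an unadjusted p under 0.05, DESeq2 called 7 higher and 3 lower, and limma-voom 0. The most abundant, histone H3.3 (c774652_g1_i1), was at 283 ± 160 CPM in leaves and 371 ± 163 in roots. The list summed to 4971 CPM in roots 2, against 1531 in roots 8 and 1487 ± 428 in leaves. Without roots 2 its median was -0.18, against -0.72 for all contigs tested then. With the number 2 libraries exchanged it was -0.56 (adjusted p 0.928), against -0.19 for all contigs.

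The terms of the heat shock and dehydration list were set beforehand as a marker of sample handling. Its transcripts were higher over 89 tested contigs of 252 matched (median 0.68, camera adjusted p 3.48e-05, adjusted p = 0.239 with an estimated correlation). In edgeR 5 rose, and 18, all higher, passed when adjusted over the list alone. Besides the class IV protein, and chosen after their values were seen, these were heat shock 70 kDa protein 8 (c798211_g1_i5, 22.4 ± 4.69 CPM in leaves, 272 ± 216 in roots), a mitochondrial small heat shock protein (c796287_g3_i2, 8.59 ± 3.76 and 147 ± 51.4), a class I small heat shock protein (c676051_g1_i1, 2.39 ± 0.319 and 172 ± 121) and a late embryogenesis abundant protein (c760180_g1_i1, 0.245 ± 0.303 and 110 ± 121). Heat shock cognate 70 kDa protein 2 (c795392_g4_i3), the most abundant, was at 5130 ± 1606 CPM in leaves and 4834 ± 345 in roots. The 5 calls were lost without leaves 5 (adjusted p 0.0661 to 0.158), leaves 6 (0.0846 to 0.165) and roots 2 (0.0809 to 0.444), and 1 held without leaves 8 (0.0455) or roots 8 (0.0263). The list median was -0.02 without roots 8, against -1.38 for all contigs tested then. With no count filter it was -0.62 (camera adjusted p 2.62e-08), against -2.28 for all contigs. In both settings it stayed above the median of all contigs.

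Storage and defence transcripts were higher as a list, over 132 tested contigs of 301 matched (median 0.53, camera adjusted p 0.0205, adjusted p = 0.418 with an estimated correlation). In edgeR 1 rose and 3 fell, and 19 were higher and 12 lower when adjusted over the list alone. All 4 were chosen after their values were seen. Endochitinase EP3 (c687963_g1_i1, 124 ± 71.2 CPM in leaves, 1.78 ± 0.244 in roots), patatin-like protein 2 (c696445_g1_i2, 134 ± 72.5 and 0.245 ± 0.346) and pathogenesis-related protein 1A (c775438_g2_i2, 8.73 ± 4.27 and 0 counts in both roots) fell. A glucan endo-1,3-beta-glucosidase rose (c253640_g1_i1, 2.04 ± 1.1 and 39.8 ± 32.1). Pathogenesis-related protein PR-4A (c290541_g1_i1), the most abundant by mean log2 CPM, was at 4937 ± 4245 CPM in leaves and 193 ± 143 in roots (adjusted p 0.180). The 4 calls were lost without leaves 5 (adjusted p 0.0803 to 0.155), leaves 6 (0.102 to 0.165), leaves 8 (0.0653 to 0.119), roots 2 (0.135 to 0.567) and roots 8 (0.0767 to 0.149). The list summed to 181536 CPM in roots 2, 18498 in roots 8 and 5833 to 17981 in the leaves. A ribonuclease-like storage protein of this list (c797413_g2_i1) was at 161445 CPM in roots 2 and 13855 in roots 8. Without roots 2 the list median was -0.01, against -0.72 for all contigs tested then. The list call was lost without leaves 5 (adjusted p 0.109) or leaves 6 (0.133) and with a CPM of at least 1 required in 2 libraries (0.0825). It was also lost with the number 2 libraries exchanged (median -0.15, adjusted p 0.109).

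Starch and sucrose transcripts did not pass as a list (70 tested of 139 matched, median -0.55, camera adjusted p 0.0904). The list passed without leaves 6 (adjusted p 0.0314), from numbers 2 and 8 alone (0.0151) and with a CPM of at least 1 required in 2 libraries (0.0367). In edgeR 2 fell, and 6 were higher and 6 lower when adjusted over the list alone. Both, chosen after their values were seen, were invertases, which split sucrose: an insoluble beta-fructofuranosidase (c653006_g1_i1, 181 ± 87.4 CPM in leaves, 0.970 ± 0.565 in roots) and a soluble one (c800181_g4_i5, 377 ± 114 and 5.60 ± 1.31). Their calls were lost without leaves 5 (adjusted p 0.0695 to 0.0803), leaves 6 (0.0846 to 0.0979), leaves 8 (0.0501 to 0.0518), roots 2 (0.166 to 0.214) and roots 8 (0.0930 to 0.0947). Sucrose synthase isoform 1 (c789634_g1_i1), the most abundant member, was at 254 ± 99.0 CPM in leaves and 1424 ± 1076 in roots (adjusted p 0.142).

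Nutrient and water transporters did not pass as a list (165 tested of 372 matched, median -0.34, camera adjusted p 0.819), and the median was 0.06 without leaves 2. In edgeR 4 rose and 1 fell, and 6 were higher and 4 lower when adjusted over the list alone. All 5 were chosen after their values were seen. Potassium transporter 5 (c788135_g1_i1, 0.0185 ± 0.0370 CPM in leaves, 10.1 ± 9.43 in roots), zinc transporter 11 (c773312_g3_i4, 4.71 ± 0.921 and 52.6 ± 31.5) and a pair of aquaporin PIP2-7 contigs (c724360_g1_i1, 0.125 ± 0.130 and 88.4 ± 110, and c183390_g1_i1, 0.121 ± 0.175 and 27.6 ± 25.2) rose. NRT1/PTR family 5.2 (c683013_g1_i1, 443 ± 241 and 7.32 ± 3.09) fell. The 5 calls were lost without leaves 5 (adjusted p 0.0876 to 0.146), leaves 6 (0.135 to 0.165), leaves 8 (0.0501 to 0.107), roots 2 (0.329 to 0.567) and roots 8 (0.0520 to 0.124). Aquaporin PIP1-4 (c783853_g2_i1), the most abundant, was at 1315 ± 808 CPM in leaves and 2528 ± 2168 in roots.

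Organ identity factors did not pass as a list (37 tested of 73 matched, median 0.16, camera adjusted p 0.0792). In edgeR 3 rose, and 12 were higher and 9 lower when adjusted over the list alone. All 3, chosen after their values were seen, were KNOX homeobox factors, regulators of meristems: a knotted-1-like 2 contig (c798501_g5_i1, 0.0124 ± 0.0247 CPM in leaves, 54.4 ± 11.2 in roots) and a pair of knotted-1-like 6 contigs (c778586_g1_i2, 0.516 ± 0.474 and 65.8 ± 50.1, and c800315_g8_i2, 0.811 ± 0.516 and 42.5 ± 37.2). The 3 calls were lost without leaves 5 (adjusted p 0.0639 to 0.120), leaves 6 (0.0846 to 0.150), roots 2 (0.0809 to 0.256) and roots 8 (0.0520 to 0.156), and 1 held without leaves 8 (0.0236). A WUSCHEL-related homeobox contig (c747564_g1_i1), the most abundant member, was at 126 ± 34.2 CPM in leaves and 380 ± 85.7 in roots (adjusted p 0.167). Among other settings, the list passed without leaves 2 (median 0.50, adjusted p 0.0278) and without roots 2. Without roots 2 its median was -0.11, above the -0.72 of all contigs tested then. Its median was also below 0 without leaves 5 (-0.09), leaves 8 (-0.05) and roots 8 (-0.19, above the -1.38 of all contigs tested then).

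Transcripts of other organisms took 1.23 ± 1.46% of the counts in leaves and 0.344 ± 0.0766% in roots. The leaf share was 0.499 ± 0.106% without leaves 8, which held 3.42% of its counts in this class (Wilson 95% interval 3.41% to 3.43%). The 1084 tested contigs of 80687 matched had a fitted median of -6.71 (camera adjusted p 2.06e-15, adjusted p = 0.298 with an estimated correlation). It was -3.52 with the 843 contigs at 0 counts in 1 tissue set at their bound. The count filter asks for 2 libraries, which can be any of 4 leaves but only both roots, so it favours contigs found in leaves. How much of the shift this makes was not tested. In edgeR 0 passed over all contigs or adjusted over the list alone, 5 were higher and 310 lower at an unadjusted p under 0.05, DESeq2 called 1 higher and 137 lower, and limma-voom 0. The fitted median was -6.26 without leaves 8, -6.05 without roots 2 and -5.89 without roots 8. From numbers 2 and 8 alone it turned to 0.89 and the call was lost (adjusted p 0.0984). The most abundant contig (c789012_g2_i1), a hypothetical fungal protein, was at 654 ± 361 CPM in leaves and 1193 ± 1624 in roots (adjusted p 0.771).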

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

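Tests chosen only after the result was seen were the share of land plant contigs, both tests of the rust fungus counts and the photosystem ratio of the number 2 columns. In each of 70 groups of 4 leaf values, the gap of the highest or lowest library to the next was compared with Dixon's 95% critical value. For independent normal values, chance marks about 1 in 20 groups, or 3.5 of 70, and 13 were marked. The values were not log-transformed and some groups share contigs, so 3.5 is only a rough guide.

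Photosystem transcripts summed to 16797 CPM in leaves 2, far above the 1853 to 2965 CPM of leaves 5, 6 and 8. A few genes taking most of the counts was argued against by the shares of the 10 most abundant contigs of each library. They took 9.01% to 9.96% of the counts in leaves 5, 6 and 8, and 16.9% in leaves 2. Leaves 2 stayed 8.60 times above the median of the other leaves without the 10 most abundant contigs over all libraries. That ratio adds little, since leaving out shares of this size could barely move it. Dilution of the plant transcripts in leaves 5, 6 and 8 by other organisms, organelles or rRNA was argued against too, as land plant contigs held at least 86.3% of their counts. A different state of the sampled leaf, such as its age or light, and a mislabelled sample from outside the series stay open, and neither was tested.

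Transcripts assigned to rust fungi, which are leaf parasites, took 1.62% of the counts of leaves 8 (271061 counts). Whether plant transcripts were assigned to rust fungi by mistake could not be decided. Of 3692 such contigs with at least 10 reads in leaves 8, 2.06% had as many in another leaf, against 96.9% of 20743 land plant contigs. But leaves 2, 5 and 6 held only 598, 890 and 4279 such counts in all. Most of these contigs could not reach 10 reads there, so the low share restates the pattern. Reads carried over from another library of the series were argued against, because no other library held more than 4279 such counts. Misassigned plant transcripts, infection of the sampled leaf and contamination from outside the series stay open. The design names no infected group, so no biological explanation was tested. In leaves 8, other fungi took 1.73% of the counts. The class of all other organisms, which includes rust and other fungi, took 3.42% and summed to 31095 CPM over the contigs of that list.

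The separate file recorded under leaves 2 is named as the root, and the reverse. By best protein hit, its counts correlated more closely with the whole-series column titled roots 2 (Spearman 0.809) than with that titled leaves 2 (0.690), a difference of 0.118, so the separate files may be recorded under each other's sample. The file recorded under roots 2 correlated at 0.738 with leaves 2 and 0.719 with roots 2, a narrow difference. Exchanged titles on the whole-series columns were argued against, since the column titled leaves 2 held 9.53 times the photosystem sum of that titled roots 2. A sample swapped with one outside the series stays open and was not tested.

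Other values far from the rest of the leaves were as follows. Nutrient and water transport summed to 12468 CPM in leaves 8, with 9867 CPM the next highest. Dammarenediol synthase (c762312_g1_i2) reached 87.5 CPM in leaves 6, with 16.1 CPM the next. In leaves 2, protopanaxadiol 6-hydroxylase (c577086_g1_i1) reached 269 CPM, with 62.5 the next. There too the photosystem II 10 kDa polypeptide (c797256_g1_i1) reached 1799 CPM, with 411 the next. Shikimate O-hydroxycinnamoyltransferase (c777502_g2_i1) reached 3224 CPM in leaves 2, with 769 the next. Histone H3.3 (c774652_g1_i1) reached 520 CPM in leaves 2, with 235 the next. GBR3 (c796492_g2_i2) reached 3534 CPM in leaves 6, with 1633 the next. Ribosomal protein L32-1 (c661731_g1_i1) was at 822 CPM in leaves 8, below the 1498 CPM of the next lowest.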

How the results depend on the processing

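Tests chosen only after seeing the data were the first and second rounds of list matching and the fit without the 10 most abundant contigs. The count of 172 contigs stayed within 1.5 times under median-ratio factors, library size alone, the CPM filter, limma-voom, a log2 change of at least 1, leaving out contigs of other organisms, organelles and rRNA and the fit without the 10 most abundant contigs. It was 2753 by DESeq2 (1326 higher, 1427 lower) and 3096 with no count filter (1557 higher, 1539 lower). On FPKM, limma called 402 contigs with a pseudocount of 1 (225 higher, 177 lower), 347 with 0.1 (124 higher, 223 lower) and 267 with 5 (184 higher, 83 lower). Counts summed by best protein hit gave 94 (62 higher, 32 lower), over fewer units. For the others the cause was not tested. At an adjusted p under 0.01 edgeR called 0, since its lowest was 0.0138. It called 0 with the number 2 libraries exchanged (1597 at an unadjusted p under 0.05), 0 with both left out (6105) and 0 from numbers 2 and 8 alone (2117), where fewer libraries remain. Leaving out each library in turn gave 0 to 1029 contigs, with 0 to 702 higher and 0 to 327 lower. Depth limits the 41 called contigs with 3 or fewer counts in 1 tissue, whose ratios have no upper bound or a wide one.

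As a block, number gave 1812 contigs (788 higher, 1024 lower), the 172 among them, all in the same direction. Numbers 2 and 8 share only a number between tissues, which the labels do not call a pair, so a paired reading is not established. Only these 2 numbers inform the blocked contrast and the spread around it. Little spread is thus measured per contig, and the blocked count leans on spread shared across contigs. Deviations of leaves 2 and roots 2 from their tissue means correlated at 0.424 across contigs and those of number 8 at 0.320, in part by construction with 2 roots. Leaves 5 and leaves 6, which share no number with a root, also correlated positively with roots 8 (0.156 and 0.186). With the block, chlorophyll and carotenoids (0.036) and the MEP pathway (0.24) changed sign, as did beta-carotene hydroxylase (0.14), the MEP synthase (0.32), the dirigent protein (-1.38) and the fungal contig (-0.43). The cause was not tested.

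The 13 lists called by camera became 0 with an estimated correlation (2 at an unadjusted p under 0.05), 0 by fry (6 at an unadjusted p under 0.05) and 8 with the number 2 libraries exchanged, and ranged from 11 to 14 without each library. That exchange changed the sign of the median of photosystems (1.41), Calvin cycle (0.43), chlorophyll and carotenoids (0.12), the mevalonate pathway (-0.37), phytosterols (-0.20), root barrier (-0.63), leaf epidermis (0.49), storage and defence (-0.15), ribosomal proteins (-0.011) and cell division (-0.56). It did so for HMG-CoA reductase (-1.13), farnesyl diphosphate synthase (-1.69), squalene synthase (-0.78), squalene epoxidase (-2.25), dammarenediol synthase (-2.28), dammarenediol 12-hydroxylase (-1.93), protopanaxadiol 6-hydroxylase (-1.13), the photosystem II polypeptide (1.66), sterol reductase (-0.20), sucrose synthase (-0.49), aquaporin PIP1-4 (-1.48), the dirigent protein (-0.56), the lipid-transfer protein (1.87), heat shock cognate protein (0.46), early light-induced protein (-0.32), the class IV heat shock protein (-1.19) and SBT1.7 (-0.085). The exchange moves a library into each group, which is its construction. With both number 2 libraries left out, signs changed for chlorophyll and carotenoids (0.21), the mevalonate pathway (-0.030), farnesyl diphosphate synthase (-0.028), squalene synthase (-0.62), squalene epoxidase (-2.16), dammarenediol synthase (-1.08), dammarenediol 12-hydroxylase (-0.40), sterol reductase (-0.075), aquaporin PIP1-4 (-0.66), the dirigent protein (-2.49) and heat shock cognate protein (0.18).

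Leaving out each library gave medians on both sides of 0 for chlorophyll and carotenoids (-0.27 to 0.46), the mevalonate pathway (-0.20 to 0.68), the MEP pathway (-0.39 to 0.16), phenylpropanoids (-0.34 to 0.60), transport (-0.82 to 0.063), storage and defence (-0.0054 to 0.56), heat shock (-0.024 to 0.89), cell division (-0.18 to 1.25) and organ identity factors (-0.19 to 0.50). Single genes that did so were farnesyl diphosphate synthase (-0.032 to 3.34), squalene synthase (-0.76 to 1.92), squalene epoxidase (-1.86 to 0.89), dammarenediol synthase (-0.76 to 2.61), dammarenediol 12-hydroxylase (-0.086 to 2.54), protopanaxadiol 6-hydroxylase (-0.11 to 4.12), beta-carotene hydroxylase (-2.25 to 0.25), the MEP synthase (-1.50 to 0.75), sterol reductase (-0.18 to 1.07), aquaporin PIP1-4 (-0.41 to 1.66), the dirigent protein (-2.68 to 0.97), heat shock cognate protein (-0.27 to 0.13), histone H3.3 (-0.15 to 0.88) and the fungal contig (-3.83 to 1.83). Where 1 root remained it was assumed to vary like the leaves. The median of all tested contigs then also fell, to -0.72 without roots 2 and -1.38 without roots 8. The cause of the sign changes was not tested.

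From numbers 2 and 8 alone, signs changed for the MEP pathway (0.30), organ identity factors (-0.034), other organisms (0.89), the MEP synthase (0.55), the dirigent protein (-0.59) and histone H3.3 (-0.12). With counts summed by best protein hit, signs changed for the MEP pathway (0.53), organ identity factors (-0.096) and the MEP synthase (0.0023). With no count filter, signs changed for heat shock (-0.62, above the -2.28 of all contigs) and the MEP synthase (0.026). With the CPM filter, signs changed for squalene epoxidase (-0.045) and the dirigent protein (-0.042). Under library size alone, signs changed for squalene epoxidase (-0.65) and the dirigent protein (-0.60). Without the 10 most abundant contigs, signs changed for squalene epoxidase (-0.023) and the dirigent protein (-0.022). By limma-voom, signs changed for chlorophyll and carotenoids (0.13), the MEP pathway (0.039), squalene epoxidase (-0.39), the dirigent protein (-0.76) and the fungal contig (-0.73). On FPKM with a pseudocount of 1, signs changed for organ identity factors (-0.25), squalene epoxidase (-0.58), 2-hydroxy-acid oxidase (-0.038), the dirigent protein (-1.03) and the fungal contig (-1.10). With a pseudocount of 0.1, signs changed for phenylpropanoids (-0.012), squalene epoxidase (-0.61), 2-hydroxy-acid oxidase (-0.041), the dirigent protein (-1.06) and the fungal contig (-1.14). With a pseudocount of 5, signs changed for organ identity factors (-0.11), squalene epoxidase (-0.47), 2-hydroxy-acid oxidase (-0.030), the dirigent protein (-0.94) and the fungal contig (-0.94). As first matched, the sign changed for organ identity factors (-0.0086). The cause was not tested. None of the sign changes under these settings, apart from those of the heat shock, phenylpropanoid and other organism lists, concerned a list or gene that had passed.

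Of 38 named genes, DESeq2 called 7 that edgeR did not, and the fit with no count filter 8. Of the 11 named genes that passed, 4 were lost with counts summed by best protein hit, 1 under library size alone and 1 by limma-voom. Without the 10 most abundant contigs, group means of the shares of counts for photosystems, organelle genomes and other organisms moved by less than the spread between replicates. The organelle share fell from 1.39% to 0.850% in leaves, and in leaves 2 alone from 1.82% to 0.906%.

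List calls in the same direction were lost, with the adjusted p in brackets: with both number 2 libraries left out for Calvin cycle (0.0787) and phytosterols (0.153), as first matched for saponins (0.282), as matched second for saponins (0.468), with the block for phytosterols (0.0645), phenylpropanoids (0.244) and storage and defence (0.113), from numbers 2 and 8 alone for phytosterols (0.138), phenylpropanoids (0.698) and storage and defence (0.662) and with the CPM filter for phenylpropanoids (0.337) and storage and defence (0.0825). The same held on FPKM with a pseudocount of 1 for phenylpropanoids (0.0626), on FPKM with a pseudocount of 5 for phenylpropanoids (0.11) and leaf epidermis (0.209), without contigs of other organisms, organelles and rRNA for phenylpropanoids (0.0700), with counts summed by protein for phenylpropanoids (0.0871) and with no count filter for leaf epidermis (0.737). Lists gained a call, with the adjusted p in brackets: with no count filter for chlorophyll and carotenoids (6.53e-04), the mevalonate pathway (7.54e-05), the MEP pathway (0.0127), transport (4.73e-04) and organ identity factors (1.97e-07), with counts summed by protein for the mevalonate pathway (0.00170), as first matched for the mevalonate pathway (0.0493), from numbers 2 and 8 alone for starch and sucrose (0.0151), with the CPM filter for starch and sucrose (0.0367) and with both number 2 libraries left out for organ identity factors (0.00471). The same held under library size alone for organ identity factors (0.0486). A call was gained for organ identity factors (0.00305) with the number 2 libraries exchanged. The cause was not tested.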

Other observations

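All tests of protein families were chosen after the results were seen. Families named in the descriptions were compared with the 18900 tested contigs that have one, by a one-sided Fisher's exact test for an excess among the contigs called by edgeR, over 1816 tests. Contigs of a family are not independent, since an assembly can split 1 gene. LIGHT-DEPENDENT SHORT HYPOCOTYLS proteins, plant transcription factors of organ boundaries and meristems, had 5 of 12 tested contigs higher in roots (adjusted p 3.43e-06). Among them, number 3 (c727754_g1_i1) was at 34.2 ± 8.13 CPM in roots (SD, n = 2) and listed at 0 in all 4 leaves, and a number 10 contig (c758302_g3_i1) was at 116 ± 112 CPM in roots and 1.1 ± 0.286 in leaves. AT-hook nuclear-localized proteins, which bind AT-rich DNA, had 5 of 35 higher in roots (adjusted p 4.29e-04), such as a number 20 contig (c854487_g1_i1) at 228 ± 232 CPM in roots and 0.275 ± 0.205 in leaves. S-adenosylmethionine synthases, which make the methyl donor used in lignin and ethylene synthesis, had 3 of 11 higher in roots (adjusted p 0.00650). Their identifiers belong to 1 assembly cluster, and the number 2 contig (c789386_g2_i1) was at 57.9 ± 22.3 CPM in roots and 0.933 ± 0.330 in leaves.

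Knotted-1-like homeobox factors (3 of 8 higher in roots, adjusted p 0.00279) and ECERIFERUM proteins (3 of 6 lower in roots, adjusted p 3.15e-04) also passed by the same exact test. The terms of their lists were written before the data were examined, but how they were matched to contigs was not fixed then. These families rest on the 172 contigs called by edgeR from all 6 libraries, of which 0 passed without leaves 5, leaves 6 or roots 2, 5 without roots 8 and 27 without leaves 8. The unadjusted p was under 0.05 for 3750, 4280 and 3194 contigs without leaves 5, leaves 6 and roots 2.

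A few transcripts took large shares of single libraries. In every library but roots 2 the largest was an rRNA repeat contig (c698379_g1_i1), from 2.64% of the counts in leaves 5 to 5.42% in leaves 2. A ribonuclease-like storage protein, of a kind abundant in ginseng roots (c797413_g2_i1), took 10.3% of the counts of roots 2 and 1.55% of those of roots 8, and did not pass (adjusted p 0.0588 in edgeR). A glycine-rich protein (c494428_g1_i1) took 4.70% of the counts of leaves 2 and 0.843% to 1.82% of those of the other leaves (adjusted p 0.0584). The number of contigs with a count was 49808 in leaves 2, 51607 in roots 2 and 56312 in roots 8, against 91296 in leaves 5, 72912 in leaves 6 and 106150 in leaves 8.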
